A study of Mus musculus with 15 samples.

How the data were processed

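Total RNA of mouse liver was labelled with Cy3 after amplification with random primers and hybridised to one-colour lncRNA and mRNA arrays, per the labels' protocols, 1 array per sample. The deposited files hold spot intensities as written by Agilent Feature Extraction 11.0.1.1, with a grid made on genome build mm9, per the file headers. The intensity used as the main value is the processed signal, which is background-corrected by that software, per the file headers. No normalization between arrays is recorded in the file headers, and later steps by the submitters are not given in the sources used here.

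Each array holds 62939 features, of which 61500 are not control spots. The 300 spots of 15 negative-control probes among these were left out, as were spots marked as non-uniform or population outliers (13 to 40 per array), and the spots of 1 probe were averaged, which left 60915 probes. The main setting was log2 of the processed signal minus the array's 75th percentile of it. Probes well above background on at least 5 of the 15 arrays were tested if they also kept an unmarked spot on every array, 34985 in all (57.4%). A mean per group was fitted to the 15 arrays together with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom), with eBayes moderation and Benjamini-Hochberg adjustment over the tested probes of a contrast, and a probe was called at an adjusted p under 0.05. Every adjusted p for a gene or probe is limma's. Tables were read with the R package data.table (version 1.17.8) and drawn with matplotlib 3.10.9. The number of arrays limits the precision.

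A RefSeq accession stood in the files for 15 tested probes, of 20 spots each, and all 15 matched a gene symbol in a RefSeq gene table of assembly GRCm38.p6, used for names only. The other 34970 tested probes have IDs of the array's design that no table used here pairs with a gene. Of the 20 gene lists and 13 cell type marker lists fixed before the data were examined, 2 had a measured member: Tfrc in the list of the hypoxia response and Hsp90ab1 in the list of heat shock proteins, 1 gene each, so that adjusted over the list alone their p is the unadjusted one. These are 0.00011 for Tfrc and 0.000184 for Hsp90ab1 in I/R against sham, 2.3e-06 and 0.00366 in IPC against I/R, and 3.67e-09 and 0.142 in IPC against sham. Tests of the lists as sets, and splits into cell types, were therefore not run. The phrase over the list alone elsewhere refers to the 15 named genes.

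The rule for named items was fixed beforehand: genes with a symbol that passed with groups that did not overlap, at most 10 that rose and 10 that fell, list members, and the lncRNA probes with the largest changes. Without a probe table, 1 unnamed probe and 1 lincRNA-named probe with the largest rise, and the same for the largest fall, are given for each of the first 2 comparisons, among probes above background on all 10 arrays. The named genes that did not pass, and those given for IPC against sham beyond the list members, were added after their values were seen, to cover all 15. A probe above background on all arrays of 1 group and on no array of the other has only a bound: the bright group's mean against the mean, per array of the other group, of the higher of the probe's own signal and the lowest signal among probes well above background.

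The 2 slides were told apart by scan time. With slide as a block, the I/R minus sham difference rests on slide 2 and the IPC minus I/R difference on slide 1. Replicate arrays were compared over 6210 single-spot probes between 2 and 6 log2 units above the 75th percentile against the noise between spots of a probe: none of the 30 pairs within a group differed by less than that noise. Repeat arrays of 1 RNA can exceed that noise as well, so the comparison cannot show whether 2 arrays carry RNA of the same mouse, and the 15 arrays were kept as separate because the labels list them as separate samples. The correlation of contrasts was set beside 100 simulations of arrays without group differences. The fits were tested on simulated data with 200 changed probes: of those changed by 1.5-fold, 2-fold and 4-fold, 55.2%, 76.1% and 95.5% were recovered in I/R against sham, with 7 false calls, and 59.7%, 80.6% and 97.0% in IPC against I/R, with 8. A simulated slide difference gave 1732 false calls in IPC against sham without the slide block and 0 with it.

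Alternatives fixed before the data were examined were quantile normalization, normexp background correction with either normalization, a 75th percentile over probes detected on all arrays, median scaling, no filter and a filter on all 15 arrays, eBayes with a trend and robust moderation, array weights, fits on the arrays of 2 groups, slide as a fixed or a random block, a replicate block, and leaving out each array. The mean signal was not among the columns used, so normexp (offset 50) took the median signal with the median background. The estimate of array weights stopped before its convergence tolerance was reached. Chance was weighed with 100 of the 126 splits of the 10 arrays of a comparison into 5 and 5, the real one included. A slide difference was weighed with all 56 splits of the slide 2 arrays into 5 and 3, all 21 of the slide 1 arrays into 5 and 2, and 100 labellings within both slides in a fit with slide as a block, tests chosen after the result had been seen. Comparisons of single values between groups used two-sided exact permutation tests.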

Results

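Liver RNA of C57BL/6 mice was measured on 15 one-colour arrays that carry probes for mRNAs and long non-coding RNAs (lncRNAs), in 3 groups of 5 arrays each. The sham group had its abdomen opened without clamping of a vessel. In the ischaemia-reperfusion (I/R) group 70% of the liver was clamped for 75 min and then reperfused for 2 h. In the preconditioned (IPC) group the same ischaemia and reperfusion followed a short cycle of 10 min of ischaemia and 10 min of reperfusion. The design text speaks of 18 mice, 6 per group, and the labels do not tie an array to a mouse, so the p-values given here measure only the spread between these arrays, which may be technical.

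The 75th percentile of the processed signal lay between 8.08 and 8.78 on the log2 scale, and 49.98% to 59.6% of the 60915 probes were well above background on an array. No spot was saturated. The arrays came from 2 slides: slide 2 held the 5 sham arrays with I/R arrays 1 to 3, and slide 1 held I/R arrays 4 and 5 with the 5 IPC arrays. Slide 1 was brighter, with 75th percentiles from 8.48 to 8.78 against 8.08 to 8.31 on slide 2. Sham and IPC arrays shared no slide, and the I/R group was on both. The first principal component held 27.3% of the variance and the second 20.8%. The 5 sham arrays had first-component scores from -60.6 to -11.7, while the I/R arrays ranged from 2.09 to 58.3 and the IPC arrays from -3.54 to 35.0.

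**Figure D1:**
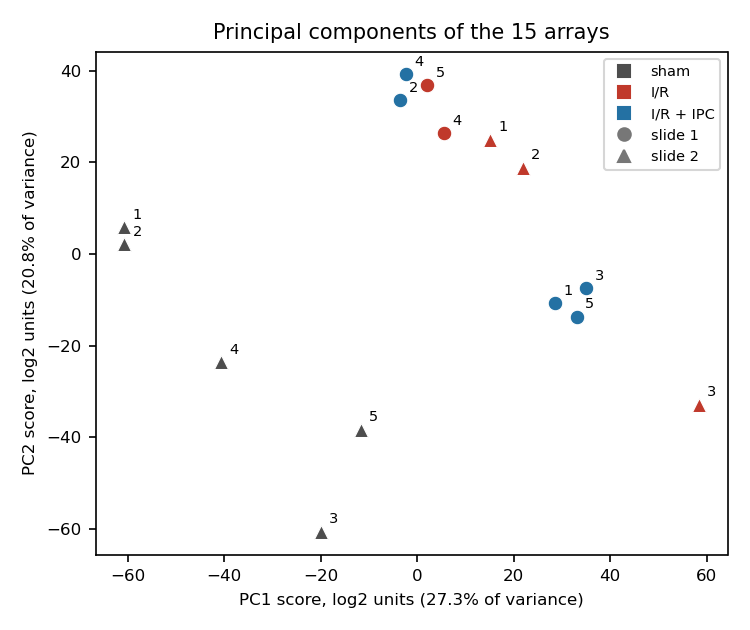
Scores of the 15 arrays on the first component (x axis, 27.3% of the variance) and the second (y axis, 20.8%), in log2 units, coloured by group, with the slide as the marker shape and the replicate number beside each point. The 5 sham arrays lie at the lowest first-component scores, and I/R and IPC arrays overlap.

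Of the 34985 probes tested, 15 carry a RefSeq accession that names a gene, and these 15 genes are the ones described by name. Most of them are used as reference genes: Actb (cytoplasmic beta-actin), Tuba1b (an alpha-tubulin), Gapdh (a glycolytic enzyme), Ppia (cyclophilin A), Hsp90ab1 (a cytosolic HSP90 chaperone), Rpl13a (a ribosomal protein), Tbp (the TATA-binding protein), Nono (a nuclear RNA-binding protein), Hprt (purine salvage), Gusb (a lysosomal enzyme), B2m (the light chain of MHC class I), Tfrc (the transferrin receptor, which takes up iron), Gk (glycerol kinase), G6pd2 and Ldhal6b. The remaining 34970 tested probes are given by the probe's own ID, since no table used here pairs them with genes.

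The first comparison asks what ischaemia and reperfusion changed in the liver against a sham operation. Actb rose 1.53-fold, from 5.42 ± 0.0521 in sham to 6.04 ± 0.0627 in I/R (log2 signal above the array's 75th percentile, SD, n = 5 per group), a difference of 0.62 with a standard error of 0.0495 and a limma adjusted p of 7.63e-07. Tfrc rose by 0.27 ± 0.0499 (SE), to 4.51 from 4.24, with an adjusted p of 0.00104. The cytoskeletal gene Tuba1b moved opposite to Actb: it fell by 0.45 ± 0.0651 (SE), from 6.22 to 5.77, with an adjusted p of 0.000144. Hsp90ab1 fell by 0.28 ± 0.0546 (SE), from 5.79 to 5.51, with an adjusted p of 0.00156.

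Among the 15 named genes, 2 rose, 7 fell and 6 did not pass the test in I/R against sham, and 11 of the 15 passed adjusted over the list alone. The other genes that fell were Ppia (-0.26), Gapdh (-0.24), Rpl13a (-0.22), Nono (-0.22) and Tbp (-0.19), all on the log2 scale. The fall of Gapdh stands beside control spots of the same gene that fell by 0.38 at the 3′ end and differed by -0.04 at the 5′ end (exact permutation p = 0.635), a comparison chosen after the data had been seen. The 6 genes that did not pass lay between -0.15 and 0.13. When slide was a block, 3 genes rose and 6 fell: Hprt joined the risen genes (0.19, adjusted p = 0.0138) and Tbp no longer passed (-0.12, adjusted p = 0.0885). Within slide 2, where all sham arrays lie, Actb differed by 0.58 (adjusted p = 0.000318), Tuba1b by -0.35 (0.00235), Tfrc by 0.32 (0.00328) and Hsp90ab1 by -0.21 (0.0158). No scaling turned the direction of a gene that passed, but under quantile normalization Gapdh (-0.09, adjusted p = 0.281) and Ppia (-0.11, 0.0787) did not pass, and under median scaling Tfrc (0.24, 0.0511), Rpl13a (-0.25, 0.0529) and Tbp (-0.22, 0.0879) did not. Over all alternatives the adjusted p ranged from 0.000214 to 0.281 for Gapdh, from 0.000425 to 0.0787 for Ppia, from 2.31e-06 to 0.0511 for Tfrc, from 0.00294 to 0.111 for Rpl13a, from 0.00122 to 0.0999 for Nono and from 0.00393 to 0.215 for Tbp.

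**Figure D2:**
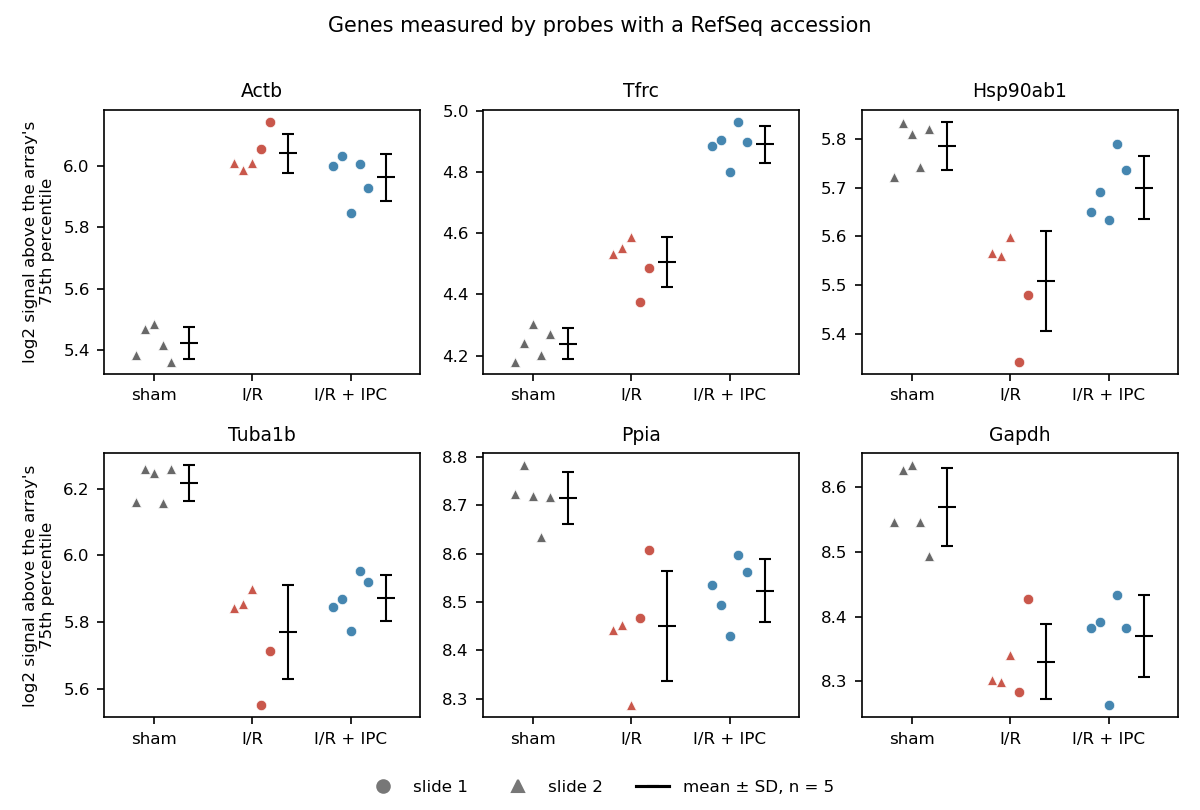
Log2 signal above the array's 75th percentile (y axis) of 6 genes in sham, I/R and IPC (x axis), 1 point per array, with the slide as the marker shape and the mean and SD of 5 arrays in black. Actb rises from 5.42 in sham to 6.04 in I/R and Tuba1b falls from 6.22 to 5.77, while Tfrc rises from 4.24 to 4.51 and to 4.89 in IPC.

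Across all probes, 10841 of 34985 (31.0%) passed an adjusted p of 0.05 in I/R against sham, 5095 higher and 5746 lower in I/R (47.0% higher). With the 75th percentile taken over probes detected on all arrays the split was 7194 higher and 4292 lower (62.6% higher). Calls numbered 4331 to 14687 over 31 alternatives. Of the calls in the main setting, 439 were higher and 211 lower by at least 2-fold. This imbalance was not kept: the counts were 477 and 517 with slide as a block, and 421 and 394 within slide 2 alone. A fit with slide as a block called 12296 (5745 higher and 6551 lower), and 9096 of them had passed without the block in the same direction. Within slide 2 alone 10111 passed, 7919 of them shared and in the same direction. The largest rise among probes measured on all 10 arrays was that of ASMM10P041195, from -1.16 ± 0.45 in sham to 1.85 ± 0.317 in I/R (SD, n = 5), 8.01-fold with an adjusted p of 3.71e-07. The largest fall among them was that of ASMM10P016002, from 5.91 ± 0.05 to 2.40 ± 0.133, 11.4-fold with an adjusted p of 4.63e-13. Probes outside this rule can have fallen further: one stood at 4.01 ± 0.0826 in sham and -2.66 ± 0.521 in I/R. A further 78 probes were well above background on all 5 I/R arrays and on no sham array. Of these, 6 had a bound of at least 2-fold, and the highest bound was 12.1-fold. Another 17 were above background on all 5 sham arrays and no I/R array, 7 with a bound of at least 2-fold and the highest at 5.49-fold.

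Probes that the array names as lincRNAs (long intergenic non-coding RNAs) numbered 436 among those tested. Of these, 78 (17.9%) passed in I/R against sham, 48 higher and 30 lower. The largest rise was that of humanlincRNA1518-_P1, by 1.33 ± 0.121 (SE, log2; adjusted p = 2.5e-06), and the largest fall that of humanlincRNA0635+_P1, at -1.27 ± 0.234 (SE; adjusted p = 0.000938). Over 26 alternatives that rise was 0.8025 to 1.435 and passed in all. The fall was -1.525 to -1.011, and its call was lost with slide as a block and the order of positions (-1.14, adjusted p = 0.0584). Blocking on slide, 117 passed, 43 higher and 74 lower, and within slide 2 alone 95 passed, 36 higher and 59 lower. The balance of rises and falls turned also without I/R array 4 (43 higher and 48 lower) and with array weights (56 and 75), and the cause was not tested.

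The second comparison asks what preconditioning changed in a liver that then went through the same ischaemia and reperfusion. Tfrc was higher still: its level was 4.89 ± 0.0593 in IPC against 4.51 ± 0.0822 in I/R (SD, n = 5), a difference of 0.38 ± 0.0499 (SE), 1.30-fold, with an adjusted p of 0.000265. Hsp90ab1, which had fallen in I/R, was 0.19 ± 0.0546 (SE) higher in IPC, at 5.70 against 5.51, with an adjusted p of 0.0476. Actb (-0.08, adjusted p = 0.423), Gapdh (0.04, 0.705) and Ppia (0.07, 0.542) did not pass.

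Of the 15 named genes, 2 rose and 13 did not pass in IPC against I/R, and 2 passed adjusted over the list alone. The 13 lay between -0.09 and 0.23. When slide was a block, 4 rose: Tfrc (0.46, adjusted p = 0.000418), Hsp90ab1 (0.29, 0.0104), Tbp (0.22, 0.0325) and Tuba1b (0.24, 0.0369). Within slide 1, which holds 2 I/R arrays and the 5 IPC arrays, Tfrc differed by 0.46 (adjusted p = 0.0275) and Hsp90ab1 by 0.29 (0.0941). The call on Hsp90ab1 was lost in 16 of 26 alternatives, with adjusted p from 0.0017 to 0.499. Among these were the fits without any 1 of I/R arrays 1, 2, 4 and 5 or of the 5 IPC arrays, where the difference of Hsp90ab1 was 0.15 to 0.21. The rise of Tfrc passed in all 26 (0.32 to 0.46, highest adjusted p 0.0421). The 26 do not include the fits without 1 sham array, each of which called 1 named gene in place of 2.

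Across all probes, 2750 of 34985 (7.86%) passed in IPC against I/R, 1218 higher and 1532 lower in IPC, with 30 higher and 22 lower by at least 2-fold. By at least 2-fold, 30 were higher and 49 lower with slide as a block, and 31 and 43 within slide 1 alone. Calls numbered 486 to 7077 over 31 alternatives, and the share of higher calls went from 44.3% to 23.2% under median scaling (324 higher and 1073 lower). The fit with slide as a block called 2549, 1560 higher and 989 lower, and 1501 of them had passed without the block in the same direction. Within slide 1 alone 888 passed (469 higher and 419 lower), of which 658 were shared and in the same direction. The largest rise was that of ASMM10P016001, from 5.47 ± 0.0701 in I/R to 7.62 ± 0.182 in IPC (SD, n = 5), 4.44-fold with an adjusted p of 2.25e-09, against 7.21 ± 0.063 in sham. ASMM10P016002, the probe with the largest fall in I/R among those measured on all 10 arrays, stood at 3.80 ± 0.0807 in IPC, between its levels in I/R and sham. The largest fall was that of ASMM10P000943, from -0.33 ± 0.116 to -2.01 ± 0.451, 3.20-fold with an adjusted p of 5.42e-05, against -1.76 ± 0.238 in sham. Of the 436 lincRNA-named probes 12 passed, 2 higher and 10 lower. Leaving out 1 array gave 5 to 14, and array weights gave 61, 46 higher and 15 lower. The largest rise among them was that of humanlincRNA0111+_P1 (0.76, adjusted p = 3.36e-05) and the largest fall that of humanlincRNA0115+_P1 (-0.92, 0.00171). Over 26 alternatives that fall was -0.99 to -0.50. Its call was lost within slide 1 alone (-0.76, adjusted p = 0.083) and with slide and row as blocks (-0.67, 0.149). It was also lost with slide as a block and the order of positions (-0.72, 0.316).

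**Figure D3:**
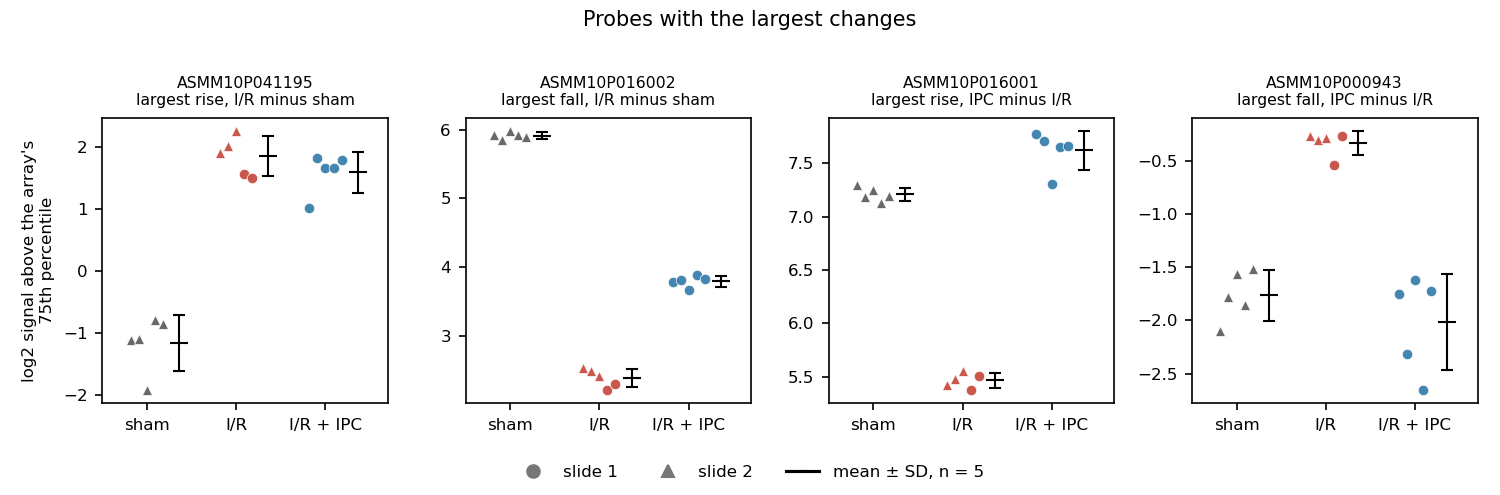
Log2 signal above the array's 75th percentile (y axis) of the probes with the largest rise and fall in I/R against sham and in IPC against I/R, in sham, I/R and IPC (x axis), 1 point per array, with the slide as the marker shape and the mean and SD of 5 arrays in black. The probes were taken from those above background on every array of the comparison. ASMM10P016001 falls from 7.21 in sham to 5.47 in I/R and stands at 7.62 in IPC, and ASMM10P041195 stands at 1.85 in I/R and 1.58 in IPC.

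Whether preconditioning moved the I/R response back was asked on arrays that were not used to choose the probes. Probes were chosen as raised or lowered on sham and 3 I/R arrays, and their IPC minus I/R difference was taken on the other 2 I/R arrays, over all 10 such splits. Raised probes, with a median first difference of 0.51, had a median IPC minus I/R difference of -0.08 (range over splits -0.12 to -0.01), and 64.7% of them were lower in IPC. Lowered probes, with a median first difference of -0.40, had a median difference of 0.04 (range -0.01 to 0.09), and 59.4% were higher in IPC. Under median scaling the medians were -0.14 for raised probes and -0.01 for lowered ones, while the median IPC minus I/R difference of all probes went from 0.01 to -0.05, a shift of raised, lowered and all probes by similar amounts. In the split that keeps each comparison within a slide, 4838 raised probes had a median of -0.01, with 52.6% lower in IPC, and 5273 lowered probes had a median of 0.02, with 53.9% higher. Across probes, which are not independent replicates, the I/R minus sham and IPC minus I/R differences correlated with r = -0.354 on all arrays. Arrays with no group difference, simulated with the same sharing of I/R arrays, gave -0.499. The covariance was -0.0334 against a simulated -0.0196. The simulation used 1 spread per probe pooled over the groups, which can be too small for the I/R arrays. Over the 10 splits, in which the 2 differences share no array, the mean r was -0.094 (range -0.206 to 0.053) and the mean covariance -0.0108. Among I/R arrays, 1 and 2 lay close together, as did 4 and 5. A split that parts such a pair may carry the same deviations into both parts. Choosing on arrays 3 to 5 and measuring on 1 and 2 parts neither pair. It gave r = 0.005, with medians of -0.11 for raised and -0.01 for lowered probes. Both differences of this split cross the slides, and a slide difference would push its r up. The split within the slides, which also parts neither pair, had the highest r of the 10, 0.053 (jackknife SE 0.196), with a covariance of 0.00635.

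The third comparison sets the preconditioned liver against sham. Tfrc was the most raised of the named genes, by 0.65 ± 0.0499 (SE), to 4.89 ± 0.0593 from 4.24 ± 0.0497 (SD, n = 5), 1.57-fold with an adjusted p of 5.33e-07. Actb rose by 0.54 ± 0.0495 (SE; adjusted p = 2.58e-06). Hsp90ab1 differed by -0.09 with an adjusted p of 0.275. Of the 15 genes 2 rose, 6 fell and 7 did not pass, and 8 passed adjusted over the list alone. The 6 that fell were Tuba1b (-0.35), Nono (-0.21), Gapdh (-0.20), Ppia (-0.19), G6pd2 (-0.19) and Rpl13a (-0.16). Blocking on slide, Tfrc (0.78, adjusted p = 3.41e-05), Actb (0.44, 0.00213) and Hprt (0.24, 0.0443) rose and Ppia (-0.34, 0.0184) and G6pd2 (-0.21, 0.0307) fell, while the differences of Tuba1b (-0.11, 0.368), Nono (-0.05, 0.691) and Gapdh (-0.24, 0.0525) did not pass and that of Rpl13a turned to 0.02 (0.861). Under quantile normalization Gapdh (-0.11, adjusted p = 0.166), Ppia (-0.08, 0.219) and Rpl13a (-0.06, 0.354) did not pass. Over 25 alternatives the call on Rpl13a was lost in 17 and its sign turned in 2, and calls were lost in 8 for Ppia, 5 for Gapdh, 4 each for Tuba1b and Nono, 2 for G6pd2, 1 for Actb and 0 for Tfrc.

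In IPC against sham 10533 probes passed, 4741 higher and 5792 lower, with 491 higher and 155 lower by at least 2-fold. With slide as a block that last balance turned, to 415 higher and 639 lower by at least 2-fold. Calls numbered 364 to 17314 over 30 alternatives, lowest with slide as a block and the order of positions and highest without a filter on dim probes. The split was 6955 higher and 4244 lower with the 75th percentile over probes detected on all arrays, and 2620 higher and 7040 lower under median scaling, where the median of all probes itself lay at -0.11. The slide block left 7319 (3824 higher and 3495 lower), 4570 of them in the same direction as without it. As no slide holds both groups, no within-slide value exists for this comparison. Among the lincRNA-named probes 77 passed, 48 higher and 29 lower, and 75 with slide as a block, 22 higher and 53 lower. Leaving out 1 array gave 62 to 92, while 572 passed without a filter on dim probes (60 higher and 512 lower) and 46 with slide as a random block. Of the 5095 probes raised in I/R against sham, 3397 were raised in IPC too, against 690.5 for independent lists of the same sizes, and of the 5746 lowered in I/R, 3760 were lowered in IPC, against 951.3. Probes that passed in both with opposite signs numbered 112. Both responses use the same sham arrays: their correlation across probes was 0.798, against 0.5003 for simulated arrays with no group difference and 0.584 (range 0.436 to 0.715) when each response had sham arrays of its own. The covariance was 0.117 against a simulated 0.0197.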

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

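The tests of the control spots were chosen after the data had been seen; the search for single arrays that stand apart followed a rule fixed before the data were examined. Among 75 groups of 5 arrays (the 15 named genes, the 8 probes given by ID in the first 2 comparisons and 2 measures of array brightness, in each of 3 groups), 5 held an array whose gap to its nearest neighbour exceeded 0.71 of the group's range. Chance gives this for 1 in 20 groups, or 3.75 of 75. All 5 were among the probes given by ID, and none of the named genes had such an array.

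For ASMM10P041195 sham array 3 stood at -1.92 against -1.12 to -0.79 for the other sham arrays, and IPC array 1 at 1.01 against 1.66 to 1.81 for the other IPC arrays. For humanlincRNA0635+_P1, I/R array 3 stood at -0.51 against 0.65 to 1.07 for the other I/R arrays. IPC array 3 stood at 7.31 for ASMM10P016001, against 7.65 to 7.77. I/R array 4 stood at -0.54 for ASMM10P000943, against -0.31 to -0.26.

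A signal outside the comparisons came from the control spots of Gapdh, placed at the 5′ and the 3′ end of the transcript with 10 spots each. The 5′ minus 3′ difference was -0.93 ± 0.0728 in sham, -0.58 ± 0.134 in I/R and -0.59 ± 0.0557 in IPC (log2, SD, n = 5). It was 0.34 higher in I/R than in sham and 0.34 higher in IPC than in sham, each with a two-sided exact permutation p of 0.00794, the smallest that 5 against 5 arrays can give (0.0179 adjusted over 18 comparisons of control spots), and every I/R and IPC array lay above every sham array. Within slide 2 the I/R minus sham difference was 0.41. There the I/R arrays lie in row 2 of the slide and sham arrays 1 to 4 in row 1. Sham array 5, in row 2, stood at -0.80, against -0.97 to -0.95 for the other sham arrays and -0.67 to -0.43 for I/R arrays 1 to 3. Position may thus account for part of the 0.41. In I/R the 3′ end fell by 0.38 against sham while the 5′ end differed by -0.04 (exact permutation p = 0.635). In IPC the 3′ end fell by 0.26 and the 5′ end rose by 0.08 (exact permutation p = 0.0238, adjusted 0.0428). The control spots of Pgk1 showed no such rise: their 5′ minus 3′ difference was -0.15 in I/R against sham, which did not pass (exact permutation p = 0.127), and fell in IPC against sham, by 0.26 (exact permutation p = 0.00794, adjusted 0.0179), with every IPC array below every sham array. Sham and IPC lie on different slides, and the Pgk1 values divided by slide: -7.94 to -7.77 on slide 1 and -7.70 to -7.51 on slide 2. Within slide 2 their I/R minus sham difference was -0.04, and within slide 1 their IPC minus I/R difference was 0.06. The Pgk1 fall in IPC against sham therefore cannot be told apart from a slide difference. No explanation of these differences was tested.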

How the results depend on the processing

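Fits with the row or the position on the slide, fits on 1 slide alone and disjoint arrays within slides were chosen after seeing the data; the other alternatives were fixed beforehand. The cause of the moves below was not tested, except that slide 1 alone, the 2-group fits and each leave-one-out fit use fewer arrays, and that fits with more terms leave fewer degrees of freedom. The count of I/R against sham stayed within 1.5 times of 10841 in 29 of 31 alternatives, that of IPC against I/R (2750) in 23 of 31 and that of IPC against sham (10533) in 26 of 30. Of 27 changes of named genes and probes, 11 passed in the same direction in all their alternatives, among them Actb, Tuba1b and Hsp90ab1 in I/R against sham and Tfrc in IPC against I/R and IPC against sham. In the others the call was lost 81 times and the sign turned 2 times: Rpl13a in IPC against sham was 0.022 with slide as a block and 0.0087 with slide and row as blocks.

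Median scaling gave 1397 calls in IPC against I/R, 1 among the named genes and 6 among the lincRNA-named probes, and medians of -0.14 for probes raised in I/R and -0.010 for lowered ones, with that of all probes shifted from 0.01 to -0.05. Without a filter on dim probes 1832 passed in IPC against I/R (1 named gene) and 17314 in IPC against sham, 572 of them lincRNA-named (60 higher, 512 lower), which concerns probes near background. Array weights gave 7077 in IPC against I/R and turned the balance of the lincRNA-named probes, to 46 higher and 15 lower of 61 in IPC against I/R and to 56 higher and 75 lower of 131 in I/R against sham, with r = -0.510 between the contrasts. That balance turned also in I/R against sham with slide as a block (43 and 74) or a random block (43 and 51), on slide 2 (36 and 59) and without I/R array 4 (43 and 48). In IPC against sham it turned with slide as a block (22 and 53), slide and row as blocks (6 and 8), normexp with the 75th percentile (39 and 67) and median scaling (35 and 39). The 2-group fit gave 1804 in IPC against I/R, with 1 named gene.

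With slide as a block 4 named genes passed in IPC against I/R and 5 in IPC against sham, r was 0.053, and raised probes had a median of -0.020 over the 7 splits that allow it. Disjoint arrays within slides gave an r of 0.053 and a median of -0.012. Slide as a random block (correlation 0.311) gave 6386 calls in IPC against sham, with 5 named genes and 46 lincRNA-named probes, and 7 lincRNA-named probes in IPC against I/R. Slide and row as blocks gave 6779 calls in I/R against sham (51 lincRNA-named), 1266 in IPC against I/R (1 named gene) and 1706 in IPC against sham (2 named genes, 14 lincRNA-named). Slide as a block with the order of positions gave 4331 (5 named genes, 21 lincRNA-named), 486 (1 and 1) and 364 (1 and 1). Slide 1 alone gave 888 in IPC against I/R, with 1 named gene.

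Leaving out 1 array gave 9367 to 11124 calls in I/R against sham, 2042 to 3521 in IPC against I/R and 9117 to 11667 in IPC against sham. In IPC against I/R it left 1 to 2 named genes and 5 to 14 lincRNA-named probes, with 5 without I/R array 2 and 6 without I/R array 5, IPC array 4 or IPC array 5. In IPC against sham the call on Ppia was lost without sham array 2 (-0.18, adjusted p = 0.0552) and without IPC array 3 (-0.17, 0.0557), and that on Rpl13a without any 1 sham array or IPC array 1, 2, 3 or 5 (-0.17 to -0.13, adjusted p from 0.0518 to 0.105).

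The replicate numbers did not pair the arrays: of 15 pairs of arrays with the same number, 5 correlated over 0.1 in their deviations from the group means (range -0.367 to 0.512). The replicate block gave 1734 calls in IPC against I/R, with 1 named gene and 6 lincRNA-named probes; medians for raised and lowered probes rested on 2 of 10 splits, since a split needed 20 chosen probes, a minimum set after seeing the data. Moderation and the fit on 2 groups leave r as it is, and r was not computed with a replicate block. Gene list tests, their estimated correlation and the mean of all probes of a gene were not run, for want of a probe-to-gene table. Signal over background limits all of this: 25881 of 60915 probes were above background on fewer than 5 arrays.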

Other observations

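The tests of the control spots, those of the slides as the source of the calls, the fits with row or position, the splits of the I/R arrays, and the row differences over bright probes and against the I/R difference were chosen after the result had been seen. Control spots for the 3′ end of Pgk1, a glycolytic enzyme induced by hypoxia, gave a level of 7.52 ± 0.0494 in sham, 7.38 ± 0.0494 in I/R and 7.43 ± 0.0567 in IPC (log2 above the array's 75th percentile, SD, n = 5). In I/R it fell by 0.14, with all 5 arrays below all 5 sham arrays and a two-sided exact permutation p of 0.00794 (0.0179 adjusted over 18 comparisons of control spots), and within slide 2 it fell by 0.15. Pgk1 was the one member of the hypoxia list measured only in this way, and under this scaling it moved opposite to Tfrc, the other measured member. No other scaling was applied to the control spots. In I/R against sham the Gapdh probe went from -0.24 to -0.09 under quantile normalization, so the direction of Pgk1 may depend on the scaling. IPC against I/R gave 0.05 (exact permutation p = 0.135).

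Chance as the source of the calls was weighed with 100 splits of the 10 arrays of each comparison, and only 1, the real one, gave 10841 calls in I/R against sham (highest other 1064), 2750 in IPC against I/R (highest other 804, from I/R arrays 1 to 3 with IPC arrays 4 and 5) and 10533 in IPC against sham (highest other 1556). If the arrays are independent, chance assignment would rarely give the 3 counts. The labels do not tie an array to a mouse, so chance is not excluded where arrays share a mouse. The real split of sham and IPC arrays is also the split by slide. Where an additive difference between the slides drops out, slide 2 alone gave 10111 calls in I/R against sham (447 in the highest other of its 56 splits), slide 1 alone 888 in IPC against I/R (350 in the highest other of 21), and slide as a block 7319 in IPC against sham (5290 in the highest other of 100 labellings within the slides). For I/R against sham such a difference is thereby excluded as the source of all calls, though it may account for part of them. The tests of the other 2 comparisons are weaker. Only 21 labellings exist on slide 1, and other labellings gave up to 5290 calls in IPC against sham. Position on the slide goes with the groups and stays open as a source: 6779, 1266 and 1706 calls passed in the 3 comparisons with slide and row as blocks, and 4331, 486 and 364 with slide as a block and the order of positions.

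The first pattern weighed is that probes moved by I/R moved the opposite way with preconditioning (r = -0.354 across probes, which are not independent replicates). Both differences contain the I/R mean with opposite sign, and on disjoint arrays, each difference within 1 slide, r was 0.053 (jackknife SE 0.196, -0.044 to 0.137 when 1 array was left out), the highest of 10 disjoint splits, which had a mean of -0.094 and a lowest value of -0.206. Most of these splits part I/R arrays that lie close together, 1 from 2 or 4 from 5, so their parts may not be independent. The split of arrays 3 to 5 from 1 and 2, which parts no such pair, gave 0.005. Both of its differences cross the slides, and a slide difference would push its r up. An r near 0 there can thus hide a negative relation and does not decide. A candidate explanation for part or all of the negative r is the sharing of the I/R arrays. The covariance was -0.0334, against -0.0196 from sharing in simulated arrays. That simulation gave each probe 1 spread pooled over the 3 groups. Over bright probes, differences between 2 I/R arrays spread by up to 0.231 across the slides and up to 0.148 within a slide. Sham and IPC pairs, all within a slide, reached 0.109 and 0.106. The simulated value can thus be too small, and the covariance does not decide. Slide 1 minus slide 2 enters both differences with the same sign, so an additive slide difference alone would push r up, not down. A reversal by preconditioning stays open: raised probes had a median IPC minus I/R difference of -0.079 over the splits (jackknife SE 0.0471, -0.118 to -0.062 without 1 array), but of -0.012 in the split within slides, where 52.6% were lower.

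The second pattern is that I/R arrays 1 to 3, on slide 2, differed from I/R arrays 4 and 5, on slide 1: 44 probes passed between them (8866 at an unadjusted p under 0.05), while the other splits of the 5 arrays into 3 and 2 gave at most 1 (at most 3060). Array 3 also stood apart from arrays 1 and 2, at 2.75 and 2.76 times the spot noise, against 1.22 times between 1 and 2, 1.34 times between 4 and 5 and 2.89 to 4.07 times across the slides. Arrays 1 to 3 lie in the second row of their slide and arrays 4 and 5 in the first, and a position effect, which could take part, should recur between the rows of other groups. The row differences within IPC and within sham correlated with r = 0.196 (0.330 over bright probes; -0.030 to 0.302 over all probes when 1 array was left out), and the I/R difference correlated with that of IPC at 0.368, the highest of 10 splits of the IPC arrays, and with that of sham, where 1 array lies in the second row, at 0.477, the highest of 5. These values go with a position effect, but the first falls to near 0 without 1 array. Limma terms fitted beside group and slide called 0 probes for row (2490 at an unadjusted p under 0.05) and 6 for the order of positions (3480). The slide term called 3358 beside group (10274), but only 9 beside group and row (4272). Slide, row and the mice themselves therefore cannot be told apart here, and no biological explanation was tested.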
